A study of Sus scrofa with 12 samples.

How the data were processed

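Yorkshire boars gave blood, and RNA of their mononuclear cells was measured on 12 spotted cDNA arrays read in 2 colours. The boars belonged to 3 genotypes of SLA-DRB1, the gene of the beta chain of the pig's DR class II molecule: allele 050502, allele 070701, and an allele called New in the labels. Each genotype had 2 animals. Per the labels' protocols, cells were separated on a density gradient without further treatment, total RNA was amplified in 1 round, and amplified RNA was copied into cDNA carrying Alexa Fluor 647 in channel 1 and Alexa Fluor 555 in channel 2. The series design text describes a loop in which each animal was hybridised with an animal of each other genotype, giving 6 hybridised pairs, and each pair was run again with the dyes exchanged.

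The spot intensity values were deposited as scanned: per the file headers, slides were read at 635 and 532 nm on a GenePix 4000B scanner, spots and local background were measured with GenePix Pro 6.0.1.25, and no normalization was applied. The percent of saturated pixels in each spot came from the same software, per the file headers, and no spot had more than 50 percent of its pixels at the ceiling. The authors' deposited value table held log2 ratios of red over green. All its values equalled the scanner software's own log ratio within 0.001, with column medians from -0.69 to 0.60, so they were neither centred nor turned for the dye exchange. It served as an alternative source only.

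Each array held 1680 spots in 4 print blocks, with 8 spots for most probes and 16 for some. Probe names were taken from the array's own columns. Of 188 gene probe identifiers, 163 were read to a single gene symbol for use in gene lists, 25 were left without a symbol, and 142 of the 158 distinct symbols stood in the pig gene table of assembly Sscrofa11.1. The probe sequences, and the species from which they were made, were not given in the sources used here, nor was the chain that each MHC class II probe detects. The array's names are therefore used throughout.

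Foreground medians were background-corrected with limma's normexp method (offset 50) and log ratios were normalized within each array by global loess, with control spots and spots marked as not found given weight 0. Spots of a probe were averaged. Ratios were turned to the first-named genotype over the second, and the arrays of a dye exchange, which share their RNA extracts, were averaged to 1 value. A probe was tested if its foreground exceeded background by 2 background SD in at least 1 channel on at least 6 of the 12 arrays, which left out 3 probes and kept 185. Controls were buffer spots, genomic DNA, and DNA of VapA, a gene of Rhodococcus equi, and of plasmid pACYC177. The last 2 served as negative controls.

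The 6 averaged ratios were fitted in limma 3.58.1 (R 4.3.3) with lmFit, followed by eBayes (prior degrees of freedom 1.85). The fit had 1 coefficient per genotype pair and 3 residual degrees of freedom shared by all pairs. It treats the 6 ratios as independent, although each animal was hybridised with each other genotype. No animal term was fitted, because the labels do not say which hybridisations share an animal. All p-values are two-sided and adjusted by Benjamini-Hochberg over the 185 probes, with 0.05 as the threshold. The SD given with a ratio is that between the 2 hybridised pairs, which hold different animals. The confidence level of intervals is 95 percent. With so few animals, the number of arrays limits the precision.

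Of 22 gene lists for blood cell types, antigen presentation, cytokines and signalling, 15 had the minimum of 3 measured genes. They were tested with camera (preset correlation 0.01), again with a correlation estimated from the data, and with fry, each adjusted over the 15 lists. Where a gene had several probes the brightest stood for it. The lists, tests and alternatives, and the rule for naming probes, were chosen before the data were examined. For each genotype pair the rule named up to 12 passing probes per direction with all 4 arrays going the same way, then probes of smallest unadjusted p up to 8 per direction, every MHC class II gene, and 4 genes of each other list that passed. Other probes named were chosen after their values were seen.

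The procedure was tested on simulated data with the noise of these arrays and 185 probes in 20 simulations. At a log2 ratio of 1 it recovered 90.0% of the changed probes for 050502 vs 070701, 89.8% for 050502 vs New and 90.8% for 070701 vs New. At 0.5 it recovered 72.2%, 73.0% and 71.0%, and false calls made up 4.48%, 4.35% and 3.77% of all calls. Over the 20 simulations, each pair had 400 probes changed at each log2 ratio of 0.5, 1 and 1.5, and 2500 unchanged. Noise was drawn independently for each probe. So large a share of changed probes makes the adjusted threshold easier to pass, so recovery in the real data may be lower. A simulated list shift of 0.2 was found in 100% of simulations for each pair. Genes of that list were simulated as independent, whereas correlations estimated for the real lists reached 0.37. The simulation therefore cannot show whether list results hold when genes are correlated. A simulated loop with 1 pair turned, or with 0 turned, was read correctly by the loop sum in 100 of 100 simulations.

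The alternatives covered background correction, normalization within and between arrays, foreground statistic, filter and treatment of dye exchange. They also covered the loop fit, scan date, the deposited value table and leaving out each hybridised pair. The normalization between arrays (limma's Aquantile) changes intensities and leaves log ratios as they were, so it could not test the ratios. An alternative that turned the pair labelled 050502 vs New replicate A, and another that kept only probes brighter than both negative controls, were added after the data were seen. Arrays of 2 hybridised pairs of different genotype pairs shared a scan date, so scan date was fitted as a random block over the 12 arrays, since it could not be estimated on the 6 averaged ratios.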

Results

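The arrays compared blood mononuclear cells of boars of 3 SLA-DRB1 genotypes, asking how expression of immune genes differs with the class II genotype. Each genotype pair was represented by 2 hybridised pairs of animals, A and B, and 4 arrays. Median spot intensity ranged over the 12 arrays from 378 to 1965.5 in the red channel and from 495 to 2040.5 in the green, against median backgrounds of 95 to 320 and 113 to 359.5. Of the 185 probes tested, 49 had a mean intensity above both negative-control DNAs. These included 14 of 17 antigen-presentation probes, 4 of 48 cytokine probes and 3 of 21 chemokine probes. Most cytokine and chemokine ratios therefore came from signals no brighter than at least 1 DNA without a counterpart in pig cells. Ratios of the arrays of a dye exchange correlated across probes with r of 0.66, 0.85, 0.19, 0.75, 0.69 and 0.73 for the 6 hybridised pairs in order. Probes are not independent replicates, so these values describe the arrays only.

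Cells of 050502 boars had more signal for 2 class II probes than cells of 070701 boars. MHC-DQ (probe AP2), a class II molecule that presents peptides to CD4 T cells, was 2.46-fold higher (log2 ratio 1.30, SD 0.05, n = 2 animal pairs, 95% interval 1.06 to 1.54, limma adjusted p = 0.00639). MHC-DY (AP5), named after a class II gene of ruminants, was 2.18-fold higher (log2 ratio 1.12, SD 0.16, interval 0.89 to 1.35, adjusted p = 0.00639). The same contrast gave 0.44 for MHC-DM (AP1), which loads peptides onto class II molecules (SD 0.33, adjusted p = 0.44). MHC-DR (AP3), named after the molecule whose beta chain defined the groups, had a ratio of 0.04 (SD 0.003, adjusted p = 0.81), which became -0.02 when arrays were centred on their medians.

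As a group, the 4 measured MHC class II genes shifted towards 050502, with a median log2 ratio of 0.78 (camera adjusted p = 7.96e-05). The adjusted p was 0.65 with an estimated correlation, and fry gave adjusted p = 0.025. Of the 4 genes, 2 passed over all probes and 3 when adjusted over the list alone. Which pig transcripts the MHC-DQ and MHC-DY probes bind is not known here, so the list may count the same signal repeatedly. The T cell list also passed (17 genes, 15 lower in 050502, median -0.10, adjusted p = 0.027), with fry adjusted p = 0.43, adjusted p = 0.69 with an estimated correlation and 0 genes passing over all probes in limma or adjusted over the list alone. Its members included TCRa, the T cell receptor alpha chain, at -0.61 (SD 0.36, adjusted p = 0.44), TCRd at -0.21, TCRz at -0.14 and CD3d at -0.14. Only 2 of these 17 genes were brighter than both negative controls. TLR and NF-kB signalling passed too (9 genes, 8 higher, median 0.12, adjusted p = 0.046), again with fry adjusted p = 0.43, adjusted p = 0.69 with an estimated correlation and 0 genes passing in limma over all probes or adjusted over the list alone. The transcription factor NFKB1 stood at 0.20, RelB at 0.11, and the receptors TLR4 and NOD1 at 0.24 and 0.09. Of these 9 genes, 2 were brighter than both negative controls, NFKB1 among them. Neither the T cell nor the TLR list passed with median centring, the first array of each dye exchange, the deposited values, or animal pair B left out. Neither passed with detection required on all arrays, a filter that can leave a list short of the minimum of 3 genes. With only the bright probes each held 2 genes and was not tested. The MHC class II list passed in each of these settings, the bright probes included.

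The other 12 lists did not pass (adjusted p from 0.087 to 0.98). Among the cell markers, 4 of 4 natural killer and cytotoxic genes had positive ratios (median 0.17, adjusted p = 0.087), as had 6 of 9 monocyte and dendritic cell genes (median 0.06, adjusted p = 0.30) and 2 of 4 B cell genes (median -0.004, adjusted p = 0.98). MHC class I and antigen processing had 6 of 7 genes with negative ratios (median -0.08, adjusted p = 0.26). For cytokines, the median of -0.01 and the mean of 0.18 differed in sign. At an unadjusted p under 0.05, 15 probes differed between the genotypes, 9 higher and 6 lower, where chance gives 9.25. Those that did not pass included CD1a,b,d, which present lipids (0.40, SD 0.21, adjusted p = 0.39), the protease granzyme of cytotoxic granules (0.35, SD 0.16, adjusted p = 0.44) and the cytokine IL18 (0.89, SD 0.51, adjusted p = 0.51). On the negative side stood Casp1, the protease that activates IL-1 beta (-0.86, SD 0.61, adjusted p = 0.43), the immunoproteasome subunit LMP2 (-0.40, SD 0.13) and TCReta (-0.43, SD 0.10).

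The largest ratios towards 050502 belonged to inflammatory genes and did not pass. IL1b, an inflammatory cytokine made by monocytes, had a ratio of 1.88 (3.67-fold, SD 0.41, adjusted p = 0.66) in limma, where the spread shared by all comparisons includes the opposed hybridised pairs of 050502 vs New. MPIb and IL8, chemokines of inflammation, stood at 1.45 and 1.33, and IL8 was not brighter than both negative controls. These probes were named after their values were seen. With the pair labelled 050502 vs New replicate A turned, the limma adjusted p was 0.0196 for IL1b and 0.0302 for IL10. IL10, a cytokine that restrains inflammation (0.51, SD 0.10), had a signal not brighter than both negative controls. Leaving out either hybridised pair of 050502 vs New, A or B, also let IL1b pass. Both give the same result by construction, since the pair that stays adds no spread to the fit. The gain was therefore not particular to the pair that was turned.

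All 4 arrays had the same direction for 54 of the 185 probes, and the ratios of the 2 animal pairs correlated across probes with r = 0.60. Leaving out animal pair A or B ended both calls (adjusted p = 0.0748 and 0.117 for each probe), with log2 ratios for MHC-DQ of 1.33 and 1.26 and for MHC-DY of 1.24 and 1.01 in the pair that stayed. Median centring ended the call of MHC-DY (adjusted p = 0.0945), and with a single array of each dye exchange MHC-DY missed the threshold on the first (0.0597) and MHC-DQ on the second (0.540). With scan date as a random block, MHC-DQ was at 1.27 (adjusted p = 0.00872) and MHC-DY at 1.098 (adjusted p = 5.58e-05), in a fit over single arrays that counts the arrays of a dye exchange as replicates. Within the only date that held 2 genotype pairs, pair A gave 1.26 for MHC-DQ, 1.01 for MHC-DY and a list median of 0.84.

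**Figure D1:**
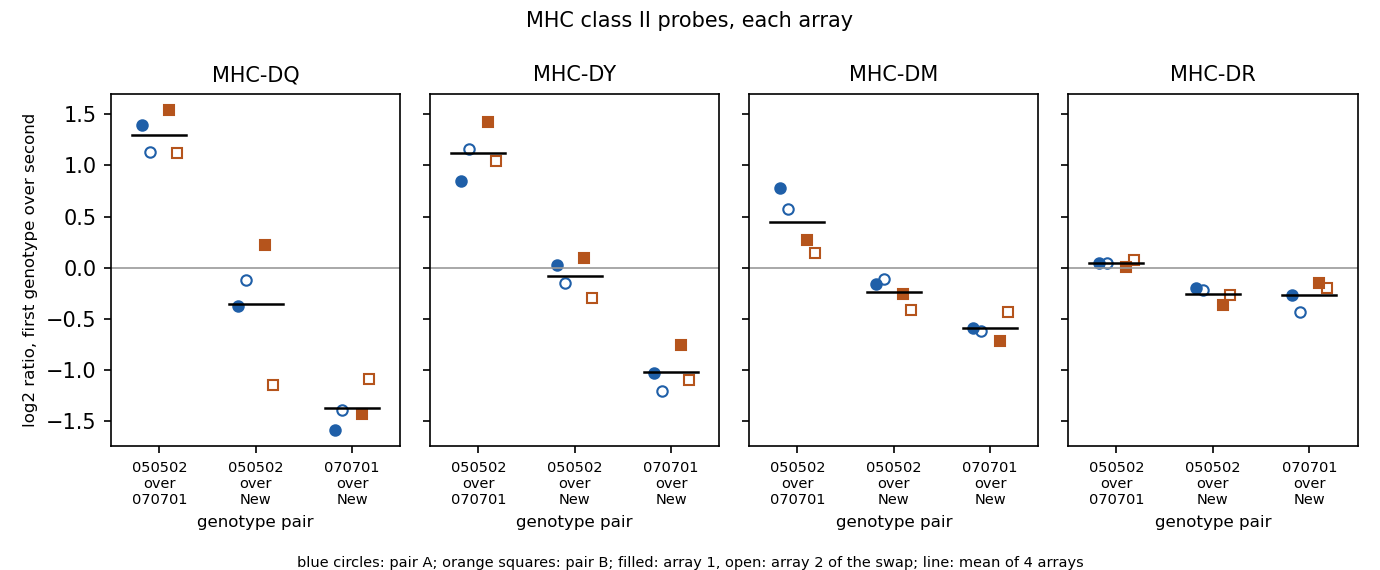
Log2 ratio (vertical axis, first-named genotype over second) of 4 MHC class II probes on each of the 12 arrays, by genotype pair (horizontal axis), with circles for animal pair A, squares for animal pair B, filled and open symbols for the arrays of a dye exchange, and a line at the mean of 4 arrays. MHC-DQ and MHC-DY lie above 0 on all 4 arrays of 050502 over 070701 (means 1.30 and 1.12) and below 0 on all 4 arrays of 070701 over New (means -1.37 and -1.02).

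Between 070701 and New boars the same 2 class II probes passed, both lower in 070701. MHC-DQ was 2.59-fold lower (log2 ratio -1.37, SD 0.16, n = 2 animal pairs, 95% interval -1.61 to -1.13, limma adjusted p = 0.0059). MHC-DY was 2.03-fold lower (-1.02, SD 0.14, interval -1.25 to -0.79, adjusted p = 0.00988). MHC-DM had a ratio of -0.59 (SD 0.02, adjusted p = 0.20) and MHC-DR of -0.26 (SD 0.12, adjusted p = 0.39). FcRN, the receptor that protects IgG from breakdown, was at 0.48 (SD 0.09, adjusted p = 0.086) and Casp1 at 1.05 (2.07-fold, SD 0.09, adjusted p = 0.19).

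The MHC class II list was the only list of 15 to pass: 4 of 4 genes were lower in 070701 (median -0.80, camera adjusted p = 2.46e-08, fry adjusted p = 0.0161), with adjusted p = 0.29 with an estimated correlation. Of the 4 genes, 2 passed over all probes and 4 when adjusted over the list alone. The other 14 lists had adjusted p from 0.61 to 0.87. They included T cells (9 of 17 genes positive, median 0.01), monocytes and dendritic cells (6 of 9 positive, median 0.03), natural killer cells (3 of 4 negative, median -0.05) and B cells (4 of 4 negative, median -0.28). Adjusted over the list alone, 1 monocyte and dendritic cell gene and 1 apoptosis gene passed, against 0 of each over all probes in limma. Housekeeping genes had a median of 0.03 and a mean of -0.48, since ACTB (beta actin) stood at -1.52 with a wide spread (SD 0.85, adjusted p = 0.53) beside GAPDH at 0.03 and HPRT at 0.06.

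At an unadjusted p under 0.05, 14 probes differed, 3 higher and 11 lower in 070701. Those that did not pass further included TCRa (0.50, SD 0.18, adjusted p = 0.53), CD1a,b,d (-0.47, SD 0.06, adjusted p = 0.19), M-CSFb, a growth factor of monocytes (-0.29, SD 0.01, adjusted p = 0.26), and FcRg (-0.43, SD 0.32, adjusted p = 0.40). The ratios of the 2 animal pairs correlated across probes with r = 0.64, and 55 probes had 4 arrays in the same direction. Leaving out an animal pair ended both calls: without pair A the adjusted p was 0.167 for MHC-DQ and 0.262 for MHC-DY, and without pair B it was 0.0901 and 0.133. The ratios in the pair that stayed were -1.26 and -0.93 without A and -1.49 and -1.12 without B. With a single array of each dye exchange MHC-DY missed the threshold on the first (adjusted p = 0.0823) and MHC-DQ on the second (0.360). With scan date as a random block, MHC-DQ was at -1.36 (adjusted p = 0.00335) and MHC-DY at -0.995 (adjusted p = 0.000146), again counting the arrays of a dye exchange as replicates. Within the shared date, pair B gave -1.26, -0.93 and a list median of -0.75. Both comparisons with 070701 rest on the same 2 boars of that genotype.

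No probe passed between 050502 and New boars (0 of 185 in limma, 15 at an unadjusted p under 0.05, 10 higher and 5 lower). The direction of this comparison is not settled, because its hybridised pairs opposed each other: their ratios correlated across probes with r = -0.54. Values are given as the labels have them and, after them, with the pair labelled 050502 vs New replicate A turned. MHC-DQ stood at -0.35 (SD 0.15, adjusted p = 0.56) and -0.11 when turned, MHC-DR at -0.26 (SD 0.08) and -0.06, MHC-DM at -0.24 (SD 0.14) and -0.10, and MHC-DY at -0.08 (SD 0.03) and -0.02. The chemokine RANTES, which attracts T cells, was at 0.57 (SD 0.36, adjusted p = 0.56) and 0.26 when turned. The same values were 0.24 (SD 0.03) and 0.02 for the cytokine IFNg, which was detected in the New channel of only 1 of 4 arrays, 0.19 (SD 0.10) and 0.07 for the bacterial sensor NOD1, -0.26 (SD 0.06) and -0.04 for CD1a,b,d, and -0.19 (SD 0.03) and 0.02 for the transcription factor NFAT1. In arrays A1 and B1 the New channel had only 76 and 90 probes detected, so low detection there was not particular to single probes of this comparison.

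As labelled, 4 lists passed, and 0 passed with the pair turned. The MHC class II list had 4 of 4 genes lower in 050502 (median -0.25, camera adjusted p = 0.016, fry adjusted p = 0.38), with adjusted p = 0.62 with an estimated correlation. Of these genes 0 passed over all probes in limma and 2 when adjusted over the list alone. When turned, its median was -0.08 (adjusted p = 0.66). With only the first array of each dye exchange, it was -0.14 (adjusted p = 0.31), and with median centring -0.50, still passing, under the labelled direction. Leaving out pair A or B gave medians of -0.33 (adjusted p = 0.070) and -0.17 (adjusted p = 0.69). The B cell list had 4 of 4 genes lower (median -0.43, camera adjusted p = 0.031), with adjusted p = 0.62 with an estimated correlation and 0.38 when turned. Its median was -0.13 in pair A and -0.47 in pair B. Its members were IgG2a at -0.64 (SD 0.72) and -0.51 when turned, IgJ, which joins antibody polymers, at -0.24 (SD 0.16) and -0.11, CD72 at -0.21 (SD 0.55) and -0.39, and IgM. IgM was not well above background in the 050502 channel of any of 4 arrays and was detected in the New channel of only 1 of 4, so no fold is given for it.

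Chemokines and their receptors had 15 of 18 genes higher in 050502 (median 0.17, camera adjusted p = 0.016), with adjusted p = 0.62 with an estimated correlation and 0.51 when turned. Their median was 0.13 in pair A and 0.25 in pair B. Examples were CCR8 at 0.19 (SD 0.03) and 0.02 when turned, MCP-2 at 0.33 (SD 0.29) and 0.21, and CCR4 at 0.31 (SD 0.10) and 0.07. Cytokines had 22 of 28 genes higher (median 0.10, camera adjusted p = 0.036), with adjusted p = 0.62 with an estimated correlation and 0.079 when turned. Their median was 0.04 in pair A and 0.15 in pair B. IL12-40 was at 0.41 (SD 0.26) and 0.18 when turned, IL12-35 at 0.18 (SD 0.05) and 0.04, and IL17 at 0.17 (SD 0.05) and -0.04. Both IL12 probes were detected in the New channel of only 1 of 4 arrays and IL17 in that of 2. By fry the B cell, chemokine and cytokine lists had adjusted p of 0.38, 0.38 and 0.49. In each of them 0 genes passed in limma, over all probes or adjusted over the list alone. Of 18 chemokine and 28 cytokine genes, 3 in each list were brighter than both negative controls. The other 11 lists did not pass (adjusted p from 0.060 to 0.73). They included T cells (12 of 17 negative, median -0.06), natural killer cells (3 of 4 positive, median 0.05) and monocytes and dendritic cells (4 of 9 positive, median -0.01 and mean 0.04).

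With the pair turned, 4 probes passed between 050502 and New, a setting chosen after the data were seen. IL1b was 4.61-fold higher in 050502 (log2 ratio 2.20, adjusted p = 0.0174), the bacterial lipoprotein receptor TLR2 2.69-fold (1.43, adjusted p = 0.0444), IL10 1.41-fold (0.50, adjusted p = 0.0444) and Casp13A 1.45-fold (0.54, adjusted p = 0.0483). As labelled these stood at 0.36, -0.11, 0.04 and -0.02. The pair was turned because it opposed its partner, and IL1b and TLR2 were among the probes that opposed most, so turning it brings their ratios together and lowers their spread. These adjusted p therefore follow in part from that choice and are not separate evidence of a difference. IL10 was not brighter than both negative controls. Without that pair, IL1b (2.56) and the chemokine MCP3 (0.72) passed, each with adjusted p = 0.0483, but this leaves 1 hybridised pair, which is assumed to vary like those of the other comparisons. MCP3 was no brighter than the negative controls, was detected in the New channel of 1 of 4 arrays, and stood at 0.39 (adjusted p = 0.34) when turned. All 4 arrays had the same direction for 17 of the 185 probes.

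**Figure D2:**
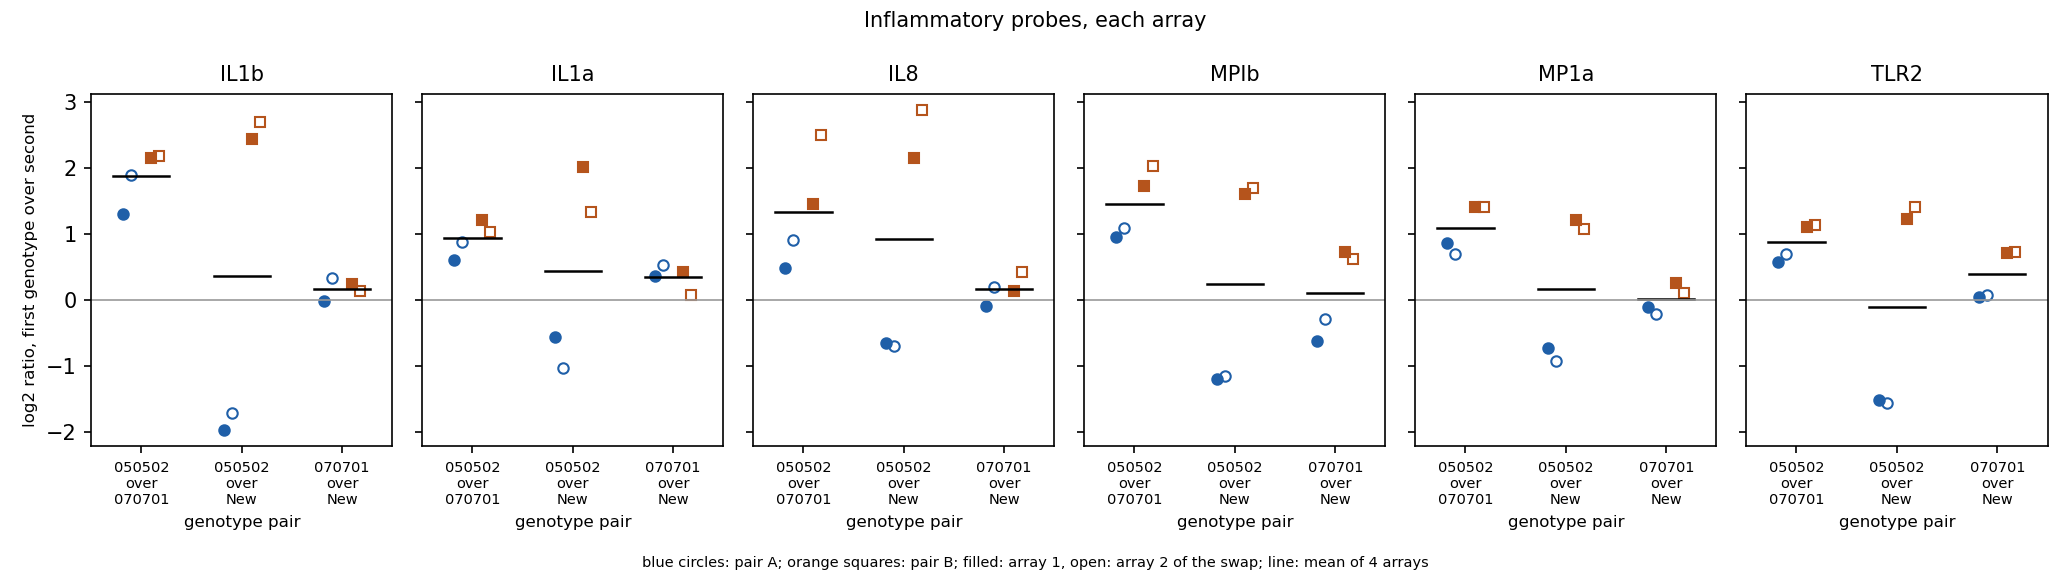
Log2 ratio (vertical axis, first-named genotype over second) of 6 inflammatory probes on each of the 12 arrays, by genotype pair (horizontal axis), with circles for animal pair A, squares for animal pair B, filled and open symbols for the arrays of a dye exchange, and a line at the mean of 4 arrays. The medians of the 6 probes are 0.76 and 1.64 in pairs A and B of 050502 over 070701, -1.01 and 1.66 in 050502 over New, and 0.05 and 0.26 in 070701 over New.

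The opposed pair was also set against the rest of the loop, since the ratio of 050502 over New can be predicted from the other 5 hybridised pairs. The pair labelled 050502 vs New replicate A correlated with that prediction at r = -0.57 across the 185 probes (95% bootstrap interval -0.70 to -0.34) and at r = -0.74 across the 49 probes brighter than both negative controls. IL1b, MPIb and TLR2 had measured ratios of -1.85, -1.18 and -1.54 in that pair. The sum of ratios around the loop had an SD of 0.574 as labelled (interval 0.432 to 0.700) and 0.306 with the pair turned (0.263 to 0.344). Differences between the arrays of each dye exchange give 0.394 (0.358 to 0.428). That figure includes any dye effect of a probe, which averaging the arrays cancels, so it may overstate the noise of the sum. These intervals, and that of the correlation, come from resampling probes, which are not independent. They hold no variation between animals or hybridisations.

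**Figure D3:**
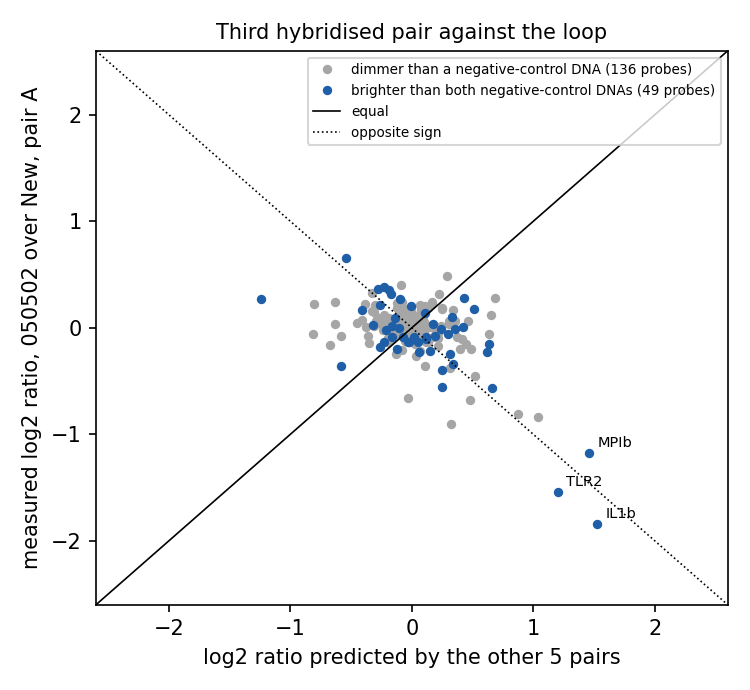
Measured log2 ratio of the pair labelled 050502 vs New replicate A (vertical axis) against the log2 ratio that the other 5 hybridised pairs predict (horizontal axis), for 185 probes, with the 49 brighter than both negative-control DNAs in blue, a solid line where both are equal and a dotted line where they have opposite sign. IL1b, MPIb and TLR2 lie near the dotted line, and the correlation over all probes is -0.57.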

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

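The tests of explanations for the 3 patterns were chosen only after the results had been seen. The checks for single arrays that stand apart followed a fixed rule.

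Among 82 groups of 4 values checked, 3 held an array far from the other arrays of its genotype pair, and chance gives about 5 percent of groups. TCRz was at -0.29 on array B1 of 050502 vs 070701, where the other arrays lay between -0.09 and -0.08. CD1a,b,d was at -0.39 on array B1 of 050502 vs New, against -0.23 to -0.21 on the others. The median green background of array B2 of 050502 vs 070701 was 113, against 150 to 157.5. In spots outside the comparisons, VapA DNA was 1.98 log2 units brighter than buffer spots as a mean of 12 arrays (1.47 to 2.45) and pACYC177 DNA 2.78 (1.89 to 3.40), although neither has a counterpart in pig cells.

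The pair labelled 050502 vs New replicate A opposed the rest of the loop. Differences between animals of a genotype cancel around the loop, if the design text is read as each animal meeting 1 animal of each other genotype, so they argue for a positive correlation with the predicted ratio, and -0.57 was found. A faulty hybridisation of a single array is argued against as well, because both arrays correlated negatively (-0.54 and -0.33). However, these arrays correlated with each other at only 0.19, and array A1 was the dimmest of the 12 in red (median 378, 76 probes detected in that channel). Low detection was not limited to this pair: array B1 of 050502 vs New had 90 probes detected in red and 53 in green. Turning the pair gave the smallest SD of the loop sum among 32 sign patterns (0.306, next 0.328 for a pattern that turns 4 pairs including this), so genotype labels exchanged on both of its arrays are a candidate explanation. Which arrays hold which animals could not be checked, and no biological explanation was tested.

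MHC-DQ and MHC-DY were lower in 070701, by a mean log2 ratio of -1.33 (SD 0.11) and -1.07 (SD 0.14) over 4 hybridised pairs that rest on 2 boars of 070701. Fewer class II-expressing cells would lower MHC-DR alike if these cells share the same proportion of both molecules, and MHC-DQ moved by -1.18 (SD 0.09) relative to MHC-DR. Allelic differences under the probes could part them too, so this cannot decide about cell numbers. An artefact of the dye or of a single array is argued against because 8 of 8 arrays had both probes lower in the 070701 channel. Allelic sequence differences under the probes may account for the pattern and cannot be told apart from lower expression: MHC-DM, whose genes vary little between haplotypes, had a mean of -0.52 (SD 0.21), a smaller shift that decides nothing, and the probe sequences were not given in the sources used here. A difference in class II expression that goes with the genotype stays open too, as untested.

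IL1b, IL1a, IL8, MPIb, MP1a and TLR2 were higher in 050502 in all hybridised pairs of that genotype except the opposed pair. A single unusual boar of 050502 is argued against, because the pairs against 070701 hold different 050502 animals, and the 6 highest probes outside class II of pair B had a median of 0.73 in pair A, and those of pair A a median of 1.26 in pair B, with 4 of the named probes in each choice. More monocytes in the 050502 samples could account for the pattern: the monocyte marker CD14 had a mean of 0.39 (SD 0.23) over 3 pairs. Its signal was not brighter than both negative controls. The other monocyte and dendritic cell probes outside the 6 lay between -0.06 (Myd-1) and 0.31 (TLR4). The only bright probe among them, CD1a,b,d, was at 0.16 (SD 0.43), so there were too few bright markers to decide. Activation of monocytes during cell preparation, and a difference between genotypes, stay open as untested.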

How the results depend on the processing

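The alternatives that turned the third pair and that kept only bright probes were chosen after the results had been seen; the other settings were fixed beforehand. In both comparisons with 070701, MHC-DQ and MHC-DY kept their direction under every setting run, with log2 ratios outside the leave-outs for 050502 vs 070701 of 1.12 to 1.47 and 1.06 to 1.14, and for 070701 vs New of -1.54 to -1.21 and -1.24 to -0.89. By camera, the MHC class II list kept its side of the threshold in both (medians 0.73 to 0.83 and -0.98 to -0.77), except with an estimated correlation. By fry it did not pass with the third pair turned (adjusted p = 0.26 for 050502 vs 070701 and 0.12 for 070701 vs New). Nor did it pass by fry in either comparison with the third pair left out. Among answers to the comparisons outside the leave-outs, 191 values kept direction and side of the threshold (counts stayed within 1.5 times), 19 weakened past it, 14 strengthened past it and 1 changed direction; within the leave-outs these were 44, 9, 1 and 0. For named probes they were 1191, 5, 44 and 26, and 394, 8, 6 and 12. Values kept outside the leave-outs include those of the normalization between arrays, which leaves log ratios unchanged. Signal not brighter than both negative controls limits most cytokine and chemokine probes, and the precision rests on 2 animal pairs per comparison. The deposited table moved the median of all probes to 0.10, 0.12 and 0.15, so its values are relative to that shift. Where a value changed, the cause was not tested unless stated. No paired analysis was possible because each array already holds both genotypes, and the labels do not say which hybridisations share a boar. Correlations of A minus B differences between the hybridisations of a genotype were -0.53 for 050502, 0.62 for 070701 and -0.43 for New. They were taken with ratios running around the loop, so that 050502 vs New was reversed. In that orientation a boar shared by equal letters would lower the correlation, and a boar shared by different letters would raise it. The signs differed between genotypes, so letters were not used to pair samples.

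Probes passing in 050502 vs 070701 numbered 2, with 6 when arrays were taken as independent, 5 with the hybridised pair and 4 with scan date as a random block, 7 in the deposited table (all higher, including IL1b, IL8, MPIb, MP1a and TLR2), 4 with the third pair turned, 1 with median centring, and 1 with the first or the second array of each dye exchange. In 070701 vs New they numbered 2, with 10, 7 and 9 in those fits of single arrays, 5 in the loop fit, 4 in the deposited table (Casp1 higher, MHC-DQ, MHC-DY and ACTB lower), and 1 with the first or second array. In 050502 vs New they numbered 0, with 1 in the deposited table (IL8) and 4 with the third pair turned. Leaving out each hybridised pair gave 0 to 3, 0 to 2 (IL1b and MCP3, without the third pair) and 0 to 3 probes for 050502 vs 070701, 050502 vs New and 070701 vs New. For 050502 vs 070701 and 070701 vs New, the 0 counts came from leaving out a pair of the comparison itself, which leaves 1 pair.

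Lists passing numbered 3, 4 and 1 in the same order, and 0 in each with an estimated correlation. Filters on probes leave fewer lists with the minimum of 3 genes. With only bright probes the T cell and TLR lists held 2 genes each and the B cell list 1, so they were not tested. For 050502 vs 070701, 1 passed with median centring, the strict filter, the first array, the deposited table, or only bright probes. For 050502 vs New, 7 passed with median centring, 1 with the strict filter, 0 with the first array, 0 with the third pair turned and 1 with only bright probes. The deposited table gave 2 for 070701 vs New. Leaving out each pair gave 1 to 3 and 0 to 5 lists for the first comparisons. The MHC class II list in 050502 vs New had a median of -0.14 (adjusted p = 0.309) with the first array, -0.077 (0.657) with the third pair turned, -0.50 with median centring (still passing), -0.49 (1.26e-05) in the deposited table, and -0.33 to -0.17 over the leave-outs. The correlation between its animal pairs became 0.54 when turned, by construction.

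Direction changed for these values that had not passed. In 050502 vs 070701, MHC-DR was -0.016 with median centring, TCRz 0.056 and CD3d 0.010 in the deposited table, and CD3d 0.17 with the first array. In 050502 vs New, turning the third pair gave NFAT1 0.025, IgM 0.28 (not well above background in the 050502 channel, so its direction is not read), IL17 -0.036, TLR2 1.43 (adjusted p = 0.0444) and Casp13A 0.54 (0.0483); the first array gave MHC-DY 0.062, IL10 -0.14 and Casp13A 0.19; the second array gave IL17 -0.062; the loop fit gave TLR2 0.35 and Casp13A 0.11. Casp13A was 0.036 with plain background subtraction, 0.0048 with print-tip loess and 0.081 in the deposited table. In 070701 vs New, the loop fit gave IL1b -0.39, IL8 -0.032, MPIb -0.33, MP1a -0.31 and TLR2 -0.068, and MP1a was -0.013 with print-tip loess, -0.0078 with median centring and -0.056 with the second array.

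Leaving out each hybridised pair gave ranges across 0 in 050502 vs New for CD72 (-0.60 to 0.18), IL1b (-1.85 to 2.56), IL10 (-0.46 to 0.54), TLR2 (-1.54 to 1.32), Casp13A (-0.56 to 0.52), MCP3 (-0.054 to 0.72), IL1a (-0.81 to 1.68), IL8 (-0.68 to 2.51), MPIb (-1.18 to 1.65) and MP1a (-0.83 to 1.14), and in 070701 vs New for MPIb (-0.45 to 0.67) and MP1a (-0.16 to 0.17).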

Other observations

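The array also carried 17 probes for hormones, hormone receptors and binding proteins, such as growth hormone, prolactin and IGF1, which no comparison singled out. In limma 0 of them passed in any genotype pair, over all probes or adjusted over these probes alone, and 0, 1 and 0 had an unadjusted p under 0.05 in 050502 vs 070701, 050502 vs New and 070701 vs New. Their log2 ratios lay between -0.20 and 0.10, between -0.26 and 0.08, and between -0.07 and 0.14. Of the 17, 2 were brighter than both negative-control DNAs. Mean log2 intensity was 7.20 for buffer spots, 9.18 for VapA DNA and 9.98 for pACYC177 DNA, and 106 of the 185 probes were brighter than VapA alone.

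With the pair labelled 050502 vs New replicate A turned, the correlation of each other hybridised pair with the ratio predicted from the remaining pairs changed from -0.16 to 0.69 and from 0.27 to 0.82 for pairs A and B of 050502 vs 070701, from 0.39 to 0.57 and from 0.17 to 0.60 for those of 070701 vs New, and from 0.84 to 0.83 for 050502 vs New replicate B. These correlations are across probes, and the comparison was chosen after the data were seen. For every pair, the measured ratio minus its prediction is the same loop sum, apart from sign. The rises therefore follow largely from the smaller SD of that sum when turned, and the pairs are not separate evidence for the turn.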
